A study of Homo sapiens with 3 samples.

How the data were processed

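Gene expression was measured in JEG-3 cells, a human choriocarcinoma cell line of placental origin, on 3 two-colour oligonucleotide arrays of the Agilent human whole genome design. Each array held 1 VPA-treated and 1 control RNA, and per the labels' protocols the VPA-treated RNA was coupled to Cy5 and the control RNA to Cy3 on every array, with no dye swap. The labels give the treatment as 48 h of valproic acid after 24 h of culture. They disagree on the dose, which the sample descriptions give as 7.83 mM and the growth protocol as 7.38 mM. The labels call the arrays biological replicates without describing the cultures, so p-values measure the spread between these 3 arrays.

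Per the file headers, the arrays were scanned on a GenePix 4000B scanner and read with GenePix Pro 5.1.0.19, which applied no normalization. The deposited scanner files hold the foreground and local background intensity of each spot in both channels, the percent of saturated pixels in each spot and a flag score of 0 for a spot that was found. The authors' deposited value table holds a linear ratio of Cy5 (VPA) over Cy3 (control) for each array. Its column medians were 1.00, 1.00 and 1.00, and its log2 values correlated across spots at 0.979, 0.988 and 0.991 with the scanner's log ratio, which settles scale, centring and direction. How the authors normalized that table, and why only 24112 of its rows are filled on all 3 arrays, is not given in the sources used here. It was used only as an alternative.

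Spot means were background-corrected with normexp at an offset of 50 and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 (R 4.3.3). Spots of a probe were averaged. Of 41000 probes, 26964 (65.8%) were kept, those with a foreground median over the background median plus 2 background SDs and no flag in at least 1 channel on all 3 arrays. Saturated spots stayed in. The log2 ratio of VPA over control was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the kept probes. Rose and fell mean an adjusted p under 0.05. A second count required a fold of at least 2. Each array is its own block in this fit. Deviations of the VPA and the control channel from their group means correlated across probes at 0.948, 0.973 and 0.951 within an array, so the array pairs the channels. Between arrays they correlated at -0.752 to 0.0175, values that centring on the mean of 3 arrays lowers. How the cultures were paired does not follow from this.

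Probe names were updated to current symbols through the accessions in the files and a RefSeq gene table of assembly GRCh38.p14. Of 41000 probes, 28573 carried a gene name, of which 22633 matched by their own accession, 538 by the accession of another hit, 2117 by symbol and 1200 by an older symbol, while 2085 kept the file's name. The remaining 12427 probes were unnamed. The hits of 322 named probes included another gene. The files name no genome build, so no coordinates are given. A gene was represented by its kept probe of highest mean signal, which gave 14122 genes. Of the 4692 genes with several kept probes, 451 had probes called in opposite directions and 4 had such probes at 2-fold or more.

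Before the data were examined, 37 gene lists and the rule for named genes were fixed. The rule takes the 12 largest increases and the 12 largest decreases among called genes with 1 sign on all arrays and signal above background in both channels, up to 4 called genes of largest change per list, 27 genes whatever their result, and up to 5 genes per direction detected in only 1 channel. Genes named outside this rule were chosen after their values were seen. Lists with at least 5 measured genes (36 of 37) were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Members called were counted with the adjustment over all probes and with adjustment over the list alone. A probe above background in only 1 channel, or saturated on all arrays of 1 channel, has only a bound, given as at least N-fold from channel values after loess and Aquantile scaling, and open to dye bias. On each array the dim channel entered at its own value, or at the lowest detected value of that channel where this was higher. A bound can therefore equal the measured mean ratio, and it then carries the spread of that ratio over the arrays.

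The fit was tested on simulated data for VPA against control over 14122 genes with the spreads of the real probes. At a simulated fold of 4 it recovered 98.0% of 50 changed genes, at 2 it recovered 84.0%, at 1.5 it recovered 46.0% and at 1.25 it recovered 4.0%, with 2 calls among 13922 unchanged genes. Far fewer genes changed in the simulation than passed in the data (74.1%), so the adjustment set a stricter threshold there. These rates therefore do not measure recovery or false calls in the real fit. Camera called 0 of 36 simulated lists with no shift, and 1 of 36 when 1 list, the metallothioneins, was shifted by 1 on the log2 scale. The simulated genes were drawn independently, so these counts do not test camera where members of a list are correlated.

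The median foreground was 871, 727 and 913 in the Cy5 channel and 835, 765 and 994 in the Cy3 channel, over a median background of 40, 45 and 39 and of 54, 50 and 45. The number of arrays, 3, limits the precision. Replicate 1 was scanned on another day than replicates 2 and 3 and gives no test of its own, and each array is a slide of its own. Alternatives covered the background correction, both normalizations, the filter, the pairing of channels, the variance model, each array left out, the authors' table, a test against a fold of 1.5, the gene summary and the list test. Detection by negative control spots, spot medians in place of means, and the scan day as a term were added after the data were seen.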

Results

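The effect of valproic acid (VPA), an antiepileptic drug that inhibits histone deacetylases, on gene expression was measured in JEG-3 cells, a human placental choriocarcinoma line. VPA-treated cells, harvested after 48 h, were set against control cells on 3 two-colour arrays, 1 per biological replicate. Between 73.6% and 80.1% of spots lay above background in the VPA channel and between 67.5% and 69.4% in the control channel. The log2 ratios of VPA over control correlated across probes at 0.926 to 0.957 between the 3 array pairs, and probes are not independent replicates. All errors below are SDs over the 3 arrays.

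Among genes above background in both channels on all 3 arrays, the largest increase was that of ALPG, an alkaline phosphatase of the placental and germ cell type, at 16.4-fold (log2 ratio 4.04 ± 0.15, n = 3, adjusted p = 7.79e-05, VPA signal saturated on 1 array). It was followed by TMSB15A, a thymosin that binds actin (15.3-fold, 3.94 ± 0.31), PRKAR2B, a regulatory subunit of protein kinase A (11.2-fold, 3.49 ± 0.21), the cancer-testis gene PAGE4 (9.64-fold, 3.27 ± 0.13), the neuronal kinesin KIF5C (9.57-fold, 3.26 ± 0.21) and FABP7, the fatty acid binding protein of brain (9.51-fold, 3.25 ± 0.09). TMSB15A had a mean control signal of only 7.01 on the log2 scale. Its log2 ratio was 4.77 with the scanner software's unnormalized medians and 4.62 with the authors' table, so its rank may depend on the processing. RILPL2, LGALS1 (galectin-1), UBE2L6, PMEL (a melanosome protein), NLRP1 and MT2A rose between 5.82-fold and 6.75-fold. The largest decrease among these genes was that of COL17A1, the hemidesmosomal collagen, which fell by 3.94 ± 0.17 on the log2 scale, a 15.4-fold difference seen by both of its probes (-3.94 and -3.85). JADE2 (-3.32 ± 0.11), LHB, which encodes the beta subunit of luteinizing hormone (-3.30 ± 0.20), VTCN1, a B7 family member (-3.18 ± 0.13), ENDOU, a placental endoribonuclease (-3.04 ± 0.43), and BRF1 (-2.98 ± 0.73) followed. CGB3, CSF3R (the receptor of granulocyte colony-stimulating factor), CLCA2, MARVELD1, S100A14 and CRACDL fell between 6.07-fold and 7.84-fold. The LHB and CGB3 probes had like control signals (14.8 and 14.8 on the log2 scale). The listed hits of the LHB probe name no other gene, but whether it also reads CGB transcripts was not tested. The rule that picked these 24 genes required 1 sign on all 3 arrays. Outside the limit on detection, with 1 channel not above background on every array, some genes moved further than several of them, such as SEMA3C (4.41), FYB1 (3.65) and ID1 (3.08) upwards and MX1 (-3.12) and INPP5D (-3.07) downwards. For NLRP1 and BRF1 the change rests on the brightest probe, since the other probes of NLRP1 gave 0.05 and -0.10 (neither past the threshold), those of BRF1 gave -0.23 and -0.45, and the mean over probes was 0.85 for NLRP1 and -1.22 for BRF1. Averaging over its 3 probes also moved JADE2, to -2.65.

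**Figure D1:**
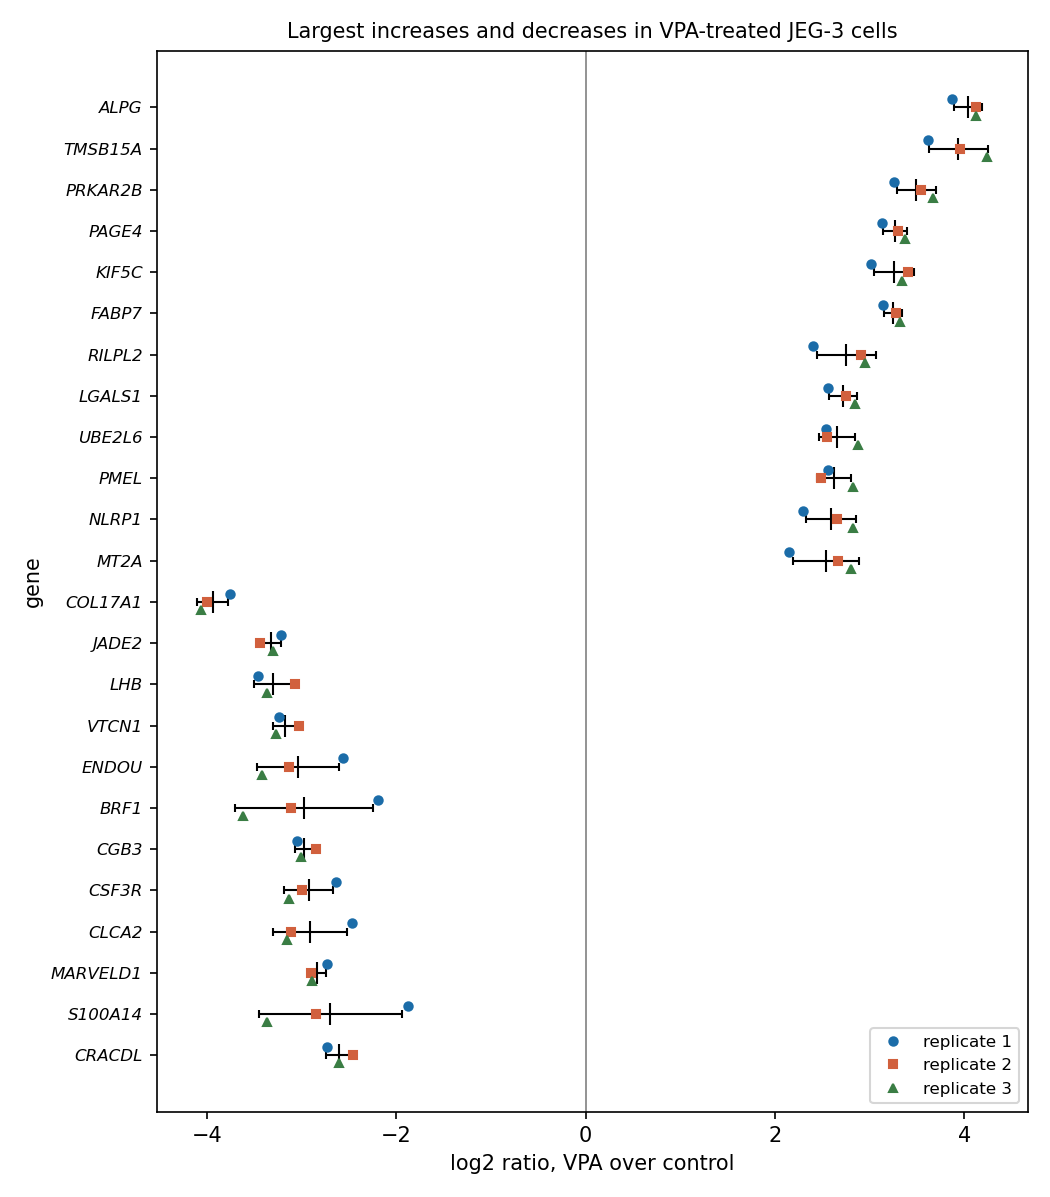
Log2 ratio of VPA over control (x axis) for the 12 genes with the largest increase and the 12 with the largest decrease among genes above background in both channels on all arrays (y axis), one symbol per array, with the mean as a bar and the SD over 3 arrays as whiskers. ALPG stands highest at 4.04 and COL17A1 lowest at -3.94, and BRF1 and S100A14 have the widest spreads, 0.73 and 0.76.

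Of 14122 genes measured, 5215 rose and 5244 fell (limma, adjusted p under 0.05), 74.1% of all. At 2-fold or more, 616 rose and 648 fell, 8.95% of all genes, and 6697 of the 10459 called genes (64.0%) changed by less than 1.5-fold. By probe, 19532 of 26964 (72.4%) passed, 9943 of them higher and 9589 lower. Every ratio shares 1 dye orientation, so a reproducible dye effect on a single gene cannot be separated from VPA. With the channels treated as unpaired samples in place of the array as a block, 1693 genes passed, 956 of them among the 1264 changed 2-fold or more, 66 of the 188 genes picked by the naming rule lost their call, and a test against a fold of 1.5 left 2034. Within the scan day shared by replicates 2 and 3, 10370 genes passed, and with the scan day as a term 10894.

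Among placental hormone genes, the subunits of chorionic gonadotropin moved apart. CGA, the common alpha subunit, rose 2.25-fold (1.17 ± 0.10, n = 3), with its VPA signal saturated on 2 arrays and its other 2 probes at 0.93 and 0.71. CGB3, the beta subunit, fell by 2.97 ± 0.10, read by a probe that also matches CGB5, CGB7 and CGB8. Of 14 measured hormone genes 7 rose and 4 fell, including a rise of CSHL1 (1.57 ± 0.10), CSH1 (placental lactogen) at 0.50 ± 0.14, above background on 1 control array, and at least 5.02-fold for TAC3, which encodes neurokinin B and was not above background on any control array. EBI3 fell by 1.84 ± 0.08 on the only probe kept. A brighter probe of EBI3, removed by the background rule, gave 0.29 without that filter and with detection by negative control spots. The list as a whole was not shifted (camera adjusted p = 0.84). All 4 measured pregnancy-specific glycoprotein genes fell, PSG8 by 0.75 ± 0.04, PSG11 by 0.72 ± 0.08, PSG6 by 0.63 ± 0.15 and PSG4 by 0.48 ± 0.07, too few for the list test. The probes of PSG8 and PSG6 also match other family members, and none of the 4 passed with the channels unpaired. PSG1 had no probe kept.

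In the steroid hormone synthesis list 9 of 17 measured genes rose and 6 fell, with camera adjusted p = 0.84 and a median of 0.30 against a mean of -0.0010. HSD11B2, which inactivates cortisol, fell by 1.89 ± 0.03, CYP11A1, the side-chain cleavage enzyme, fell by 1.19 ± 0.13 and SRD5A1 fell by 0.75 ± 0.03. AKR1C3 rose at least 2.69-fold, with no control array above background. CYP19A1 (aromatase) was 0.36 ± 0.02 and HSD3B1 0.35 ± 0.05. The calls of SRD5A1, CYP19A1 and HSD3B1 were lost with unpaired channels. HSD17B1 did not pass on its brightest probe (0.08 ± 0.17, adjusted p = 0.38), but 1 of its other 3 probes rose (0.80), and it passed as the mean of its probes (0.23) and without replicate 1 (0.17).

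Trophoblast transcription factors included 13 that rose and 9 that fell among 29 (adjusted p = 0.54). The inhibitors of basic helix-loop-helix factors rose together, ID2 by 3.75-fold (1.91 ± 0.05), ID3 by 3.73-fold (1.90 ± 0.05) and ID1 by about 8.47-fold (3.08 ± 0.15). The ID1 control signal averaged 9.74 on the log2 scale but passed the background rule on only 1 array. HAND1 rose 3.42-fold and GCM1, the regulator of syncytiotrophoblast formation, 1.77-fold (0.82 ± 0.02). Of 22 keratin and adhesion genes 9 rose and 11 fell (adjusted p = 0.66): KRT7 fell by 1.32 ± 0.13 and CLDN4 by 1.34 ± 0.21, while CDH1, E-cadherin, rose 2.33-fold (1.22 ± 0.04). With unpaired channels the calls of ID1, KRT7 and CLDN4 were lost. The syncytiotrophoblast list held 7 rises and 6 decreases among 17 (adjusted p = 0.84, median -0.06 and mean 0.13). It contains ALPG, ENDOU, GJA1, the gap junction protein connexin 43 (1.80 ± 0.12, above background on 1 control array, and 1.20 as the mean of its 2 probes), ERVV-1, which fell by 1.05 ± 0.20, and the fusogen gene ERVW-1, at 0.25 ± 0.04, a call lost with the scanner software's unnormalized medians (0.14) and with unpaired channels. Extravillous trophoblast genes split into 8 that rose and 8 that fell of 18 (adjusted p = 0.88). PLAC8 fell by 2.12 ± 0.11, FSTL3 by 1.87 ± 0.17 and SERPINE1 by 1.20 ± 0.02, and TIMP2 rose by 0.92 ± 0.12. HLA-G was near the threshold (-0.20 ± 0.16, adjusted p = 0.048) and lost its call without replicate 2 (-0.12) or without replicate 3 (-0.21), and also with a normexp offset of 10, median centring, no filter, negative control detection, unpaired channels or the authors' table (-0.08).

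Of the deacetylases themselves, HDAC2 rose 1.76-fold (0.82 ± 0.09), and HDAC7 and HDAC6 fell by 1.18 ± 0.15 and 1.10 ± 0.07, whereas HDAC1 (0.04 ± 0.06) and HDAC3 (0.07 ± 0.12) did not pass. In that list 4 of 16 genes rose and 7 fell (adjusted p = 0.84). Histone genes fell more often than they rose, 13 against 5 of 22, without passing as a list (adjusted p = 0.29). The H2B genes H2BC12, H2BC11, H2BC21 and H2BC5 fell by 1.36, 1.16, 1.08 and 0.89, and H1-0, a linker histone, rose 1.41-fold (0.49 ± 0.04). Among DNA methylation and polycomb genes 12 rose and 9 fell of 24 (adjusted p = 0.84). DNMT3L, DNMT3A and DNMT1 fell by 1.02 ± 0.04, 0.79 ± 0.10 and 0.51 ± 0.10, DNMT3B rose by 0.42 ± 0.06, and TRDMT1, an RNA methyltransferase, rose (1.73 ± 0.37, above background on 1 control array).

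Genes of DNA replication fell in 18 of 29 cases and rose in 3, namely TIPIN (2.83-fold), RRM2 (0.34) and SLBP (0.26). TYMS, thymidylate synthase, fell by 1.38 ± 0.10, UNG, which removes uracil from DNA, by 1.31 ± 0.07 and the recombinase gene RAD51 by 1.10 ± 0.12. The list did not pass (adjusted p = 0.073, and 0.045 without replicate 3). In the G2 and mitosis list 14 of 29 fell and 3 rose (adjusted p = 0.11). KIF20A fell by 1.37 ± 0.02, CCNB2 by 1.20 ± 0.12, KIF2C by 1.16 ± 0.21, AURKB by 1.02 ± 0.10 and the proliferation marker MKI67 by 0.82 ± 0.06, and the other CCNB2 probe rose (0.47), leaving a mean of -0.37. Cell cycle inhibitors and p53 targets moved both ways, 10 up and 11 down of 27 (adjusted p = 0.88). CDKN1A, the inhibitor p21, did not pass on its brightest probe (-0.12 ± 0.15, adjusted p = 0.16), while its other probe fell by 0.77 and the mean of both passed (-0.44), as did the brightest probe without replicate 1 (-0.20), with array weights or with a scan day term. CDKN2C rose (0.87 ± 0.15) and GADD45G fell by 1.09 ± 0.57. CCND1 did not pass on its brightest probe (0.34 ± 0.30, adjusted p = 0.051) but rose on its other 2 probes (0.36 and 0.61), as the mean of its probes (0.43) and without replicate 2 (0.36), among other settings. MYC rose 1.68-fold (0.75 ± 0.10). Apoptosis regulators were also split, 11 up and 10 down of 28 (adjusted p = 0.84), with CYCS (0.99 ± 0.04) and CASP8 (0.66 ± 0.03) higher and TNFSF10 and BAX lower (-0.83 ± 0.08 and -0.67 ± 0.20). The other probe of CYCS (0.17) and the other 2 of CASP8 (0.06 and 0.10) did not pass.

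Metallothioneins, which bind zinc and copper, were the only list to pass (adjusted p = 0.011), with 10 of 11 measured genes up, 8 of them at least 2-fold, and MT3 down (-0.78). The call was lost with an estimated correlation (adjusted p = 0.79). MT2A rose 5.82-fold (2.54 ± 0.35, its other probes at 1.74 ± 1.36 and 3.07 ± 0.33), MT1H 4.84-fold, MT1X 4.70-fold and MT1F 4.36-fold, and the probes of MT1H and MT1X also match other members. In the NRF2 and glutathione list 18 of 31 rose, 8 of these at least 2-fold, and 8 fell (adjusted p = 0.080). SRXN1 rose 3.31-fold (1.73 ± 0.03), GSTM3 3.08-fold (1.62 ± 0.12), HMOX1, heme oxygenase, 2.88-fold (1.52 ± 0.08) and FTL, the ferritin light chain, 2.40-fold (1.26 ± 0.14, VPA signal saturated on 2 arrays). Of 27 unfolded protein and amino acid stress genes 7 rose and 13 fell (adjusted p = 0.54). DDIT4 fell by 2.28 ± 0.42 and TRIB3 by 1.18 ± 0.24, and VLDLR rose by 1.05 ± 0.08.

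Glycolytic genes fell in 12 of 15 cases (adjusted p = 0.066, and 0.042 without replicate 3). PFKL, a phosphofructokinase, fell by 1.45 ± 0.07, PGK1 by 1.31 ± 0.07, hexokinase HK2 by 1.20 ± 0.05, and TPI1 was at least 2.25-fold lower, its control signal being saturated. The 3 that rose were HK1 (0.23), LDHB (0.48) and PFKM (0.69). Hypoxia and angiogenic genes comprised 8 rises and 12 decreases of 25 (adjusted p = 0.66), among them ENG, endoglin (-1.73 ± 0.06), and higher HIF1A (1.09 ± 0.06) and PFKFB3 (1.10 ± 0.16; 0.50 as the mean of its probes). Of 30 fatty acid genes 10 rose and 16 fell (adjusted p = 0.46), with FASN, fatty acid synthase, down by 1.34 ± 0.22, FADS2 down by 1.38 ± 0.16 and FABP5 up 3.10-fold. FABP4 was at least 2.94-fold higher, with no control array above background. Its log2 ratio ran from 0.63 to 2.39 over the arrays and depended on the background correction, at 1.71, 2.62 with a normexp offset of 10 and 4.49 with the scanner software's medians. Cholesterol genes rose in 13 and fell in 8 of 24 cases (adjusted p = 0.54), HMGCR, the rate-limiting reductase, by 2.21-fold (1.15 ± 0.11) and MSMO1 by 2.25-fold (1.17 ± 0.03). In the folate and one-carbon list 9 rose and 13 fell of 26 (adjusted p = 0.57). The reduced folate carrier gene SLC19A1 fell by 1.56 ± 0.07, the folate receptor gene FOLR1 rose 1.80-fold (0.85 ± 0.08), MTHFR rose by 0.99 ± 0.09 (1 of its other 3 probes gave 0.01) and SHMT2 fell by 0.97 ± 0.10. Transporters rose in 13 and fell in 7 of 25 cases (adjusted p = 0.32). ABCC4 was 3.38-fold higher (1.76 ± 0.05, above background on 1 control array), SLC7A8 2.60-fold higher, the cholesterol exporter ABCA1 lower (-1.33 ± 0.04) and ABCG2 not past the threshold (0.10 ± 0.01, adjusted p = 0.075, and 0.043 with array weights). ABCB1 had no probe kept.

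WNT genes rose in 12 and fell in 12 of 30 cases (adjusted p = 0.88, median 0.07 and mean -0.06), with the ligands WNT10B (-2.23), WNT3 (-2.08) and WNT7A (-1.32) down and the receptor FZD4 up 3.34-fold. TGF-beta, BMP and activin genes were even, 8 and 8 of 22 (adjusted p = 0.88), with SMAD1 at -1.25 ± 0.04, BAMBI at 1.08 ± 0.14 and CCN1 at 1.23 ± 0.19. Retinoid genes comprised 4 rises and 5 decreases of 13 (adjusted p = 0.84), DHRS3 falling by 1.49 ± 0.22. Of 22 homeobox cluster genes 9 rose and 4 fell (adjusted p = 0.67), PBX3 at 0.74 ± 0.05. HOXB3 fell by 0.71 ± 0.11, but a brighter probe, removed by the background rule, gave 0.33 without that filter and with detection by negative control spots. Imprinted genes rose in 9 and fell in 7 of 20 cases (adjusted p = 0.84). PHLDA2, a gene that limits placental growth, rose 4.40-fold (2.14 ± 0.58, above background on 1 control array), and IGF2 was at least 2.29-fold lower, its control signal being saturated. Matrix and mesenchymal genes rose in 15 and fell in 6 of 23 cases (adjusted p = 0.44), with COL1A2 up 2.33-fold and SPARC down by 0.82 ± 0.07. Interferon and antigen presentation genes fell in 13 of 25 cases (adjusted p = 0.26). IFITM3, IFITM2 and IFITM1 fell by 1.56 ± 0.07, 1.47 ± 0.24 and 1.18 ± 0.04, MX1 (-3.12 ± 0.26) fell with 1 VPA array above background, and the 3 that rose were IFI6 (0.90), HLA-C (0.46) and STAT1 (0.15). Cancer-testis genes rose in 14 of 20 cases, 7 at least 2-fold, and fell in 4 (adjusted p = 0.080, and 0.042 without replicate 3). Besides PAGE4, SPANXA1, whose probe also matches SPANXA2, rose 3.56-fold (1.83 ± 0.47), the germ cell helicase DDX4 2.82-fold and BRDT 2.70-fold, the last above background on 2 control arrays. Neuronal genes rose in 8 and fell in 7 of 23 cases (adjusted p = 0.88, median -0.08 and mean 0.20), led by KIF5C, ENO2 (1.56 ± 0.10) and MAPT (1.27 ± 0.22, 2 control arrays above background).

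**Figure D2:**
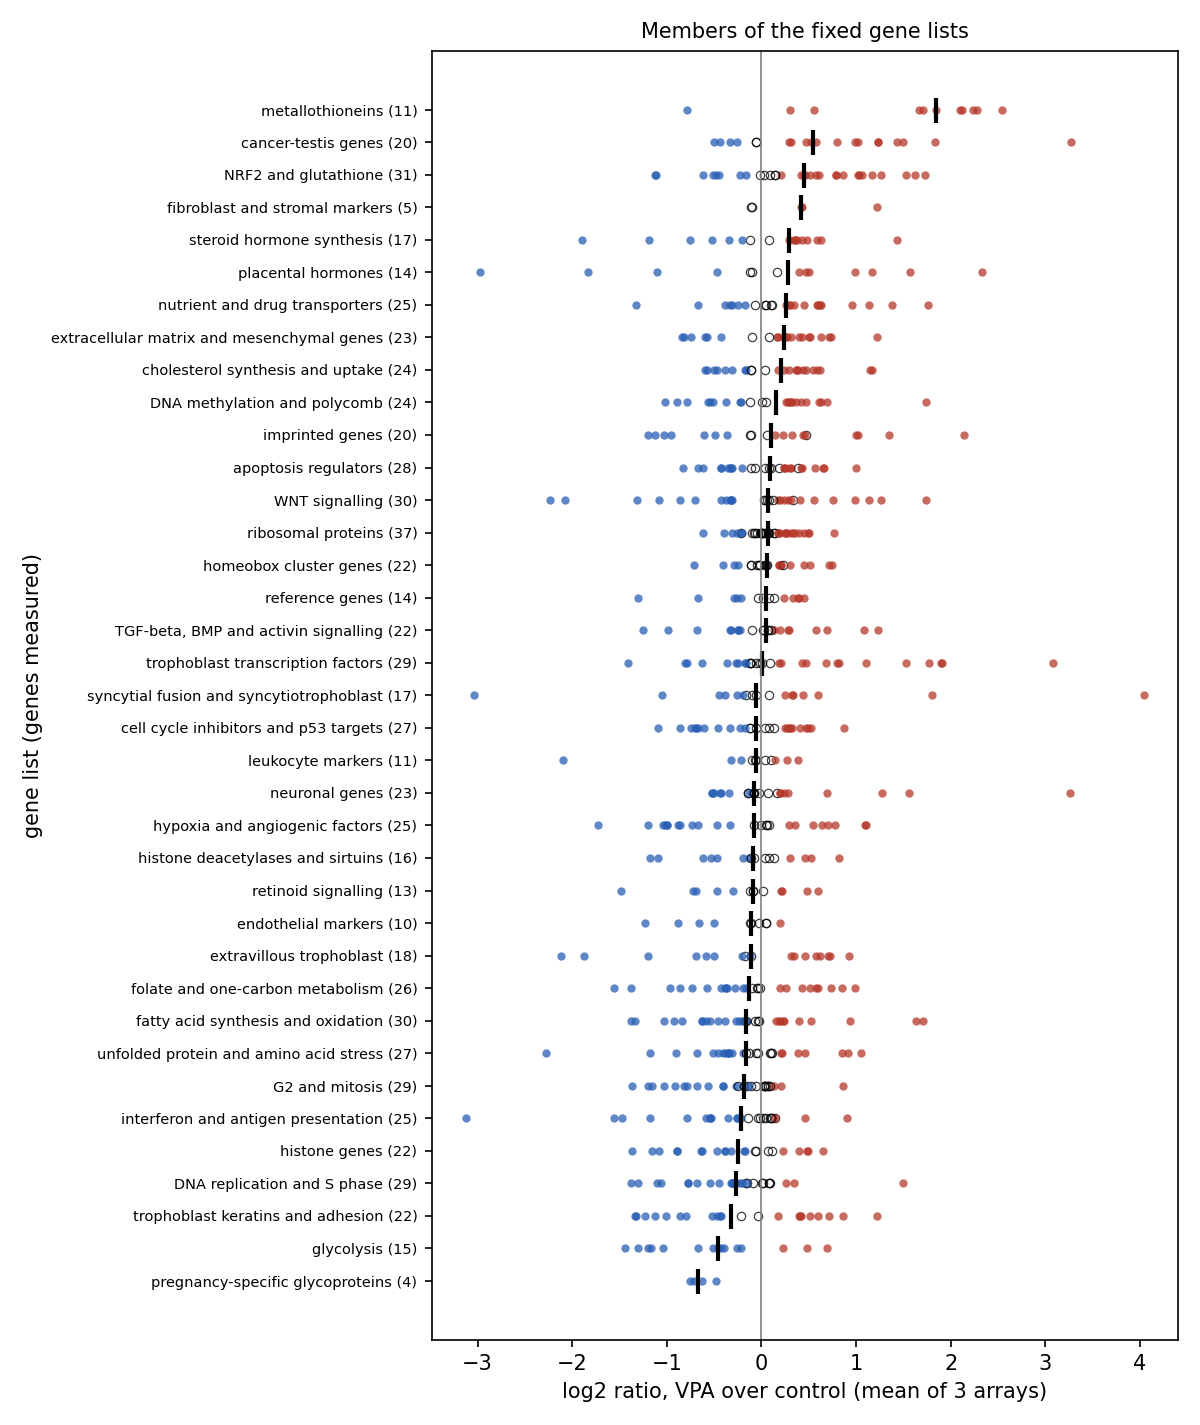
Log2 ratio of VPA over control (x axis, mean of 3 arrays) for each measured member of the 37 gene lists (y axis, number measured in brackets), with filled red points for genes that rose, filled blue for genes that fell, open points for those not past the threshold and a black bar for the list's median. The metallothionein median stands highest at 1.84 and the pregnancy-specific glycoprotein median lowest at -0.67.

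Of 37 ribosomal protein genes 14 rose, 6 fell and 17 did not pass (adjusted p = 0.53). Saturation leaves only bounds for RPLP2 (at least 1.41-fold higher), RPL24 (at least 1.28-fold higher) and RPS3 (at least 1.16-fold lower), and RPL38 (0.77) and RPL27 (0.51) were saturated with VPA on 2 arrays. Of 14 reference genes 5 rose and 5 fell (adjusted p = 0.88, median 0.05 and mean -0.05). GAPDH fell by 0.67 ± 0.09, ACTB was 0.34 ± 0.09 with the VPA signal saturated on 2 arrays and its other probes at 0.17, 0.14 and 0.06, and HPRT1 rose by 0.40 ± 0.03. Markers of other cell types gave 1 rise (PLVAP, 0.20) and 4 decreases among 10 endothelial genes (adjusted p = 0.35), 3 and 3 among 11 leukocyte genes (adjusted p = 0.84), and 3 rises (COL1A2, COL6A3 and FBLN1) with 0 decreases among 5 stromal genes (adjusted p = 0.66). CSF1R, a receptor that trophoblast also carries, fell by 2.09 ± 0.04. Adjusted over the list alone, counts differed from those above only for keratins and adhesion (12 fell), the syncytiotrophoblast list (7 fell), cell cycle inhibitors (11 rose), DNA replication (19 fell), NRF2 (19 rose), WNT (13 rose), ribosomal proteins (13 rose, 5 fell) and leukocyte markers (2 rose).

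Above background on all VPA arrays and on no control array were 265 probes, against 5 in the other direction. Detection by negative control spots gave 188 and 8, of which 15 and 0 were shared, so which probes count as detected in 1 channel depends on the rule. The largest bounds were those of DACT3 (at least 8.74-fold, adjusted p = 0.00012), the germ cell gene MAEL (at least 7.35-fold, adjusted p = 0.0020), SLC46A3 (7.11-fold, while its other kept probe, outside this set, gave a log2 ratio of 2.25 ± 0.50), SLC17A7, a glutamate transporter of synaptic vesicles (6.10-fold), and ELOVL4 (5.47-fold). Of these 5 genes SLC46A3 was also detected in VPA alone by negative control spots, which DACT3, MAEL, SLC17A7 and ELOVL4, like TAC3, AKR1C3 and FABP4, were not. For all 5, and for TAC3 and AKR1C3, the bound equals the measured mean ratio and sets no limit below its spread. That spread was widest for MAEL among the 5 (log2 ratio 2.88 ± 1.07). In the other direction, a dim probe of STK35 was at least 2.97-fold lower with VPA, while its brightest probe, above background in both channels, was 2.19-fold lower, and ITGB2 and UGT2B15 at least 1.26-fold and 1.20-fold lower, none of these by negative control spots, and ITGB2 lost its call without a filter (-0.08). The STK35 and UGT2B15 bounds also equal the measured mean ratios (log2 -1.57 and -0.26) and set no limit below their spread.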

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

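Negative control detection, spot medians and the scan day term were chosen after seeing the data. With the 6 channels unpaired and no array as a block, 2751 probes and 1693 genes passed in place of 19532 and 10459 (888 rose, 805 fell) and 6 lists in place of 1; all 1693 genes were also called in the paired fit, in the same direction, and 66 of the 188 genes picked by the naming rule lost their call, of those printed UBE2L6, PSG8, PSG11, PSG6, PSG4, SRD5A1, ID1, CLDN4, KRT7, HDAC7, H2BC21, H2BC5, GADD45G, CDKN2C, UNG, FASN, CYCS, BAX, CASP8, SHMT2, ENG, PBX3, HOXB3, IFITM2, IFITM1, DDX4, BRDT, RPL27, RPLP2, GAPDH, HPRT1, COL6A3, FBLN1, CSH1, CYP19A1, HSD3B1, ERVW-1, HLA-G, H1-0, DNMT1, MKI67, MYC, ACTB, ITGB2 and UGT2B15. The test against a fold of 1.5 left 3474 probes and 2034 genes (1032 rose, 1002 fell), as its stricter null implies. Lists past the threshold numbered 5 with the scanner software's medians, 4 without a filter and 4 with detection by negative control spots, 2 with the mean of a gene's probes, 0 with an estimated correlation and 31 with fry, which asks whether a set moves and not whether it differs from other genes. Under fry 5 lists had the opposite sign to camera, placental hormones without passing (down, adjusted p = 0.069) and 4 that passed: steroid hormone synthesis (adjusted p = 0.034), WNT (0.044), TGF-beta (0.041) and reference genes (0.0046), all down. EBI3 (0.29) and HOXB3 (0.33) turned sign without a filter, and gave 0.29 and 0.33 with negative control detection, since a brighter probe of the gene then entered. The lowest array correlation was 0.899 without a filter, and negative control detection gave 8 control-only probes. Over the arrays the median SD was 0.29 in each channel and 0.086 in the ratio. The unpaired fit therefore set the same ratios against a wider spread, which lowers its counts of probes and genes. The cause of the other shifts was not tested. Leaving out each array gave 16120 to 19346 probes, 8662 to 10370 genes (4335 to 5126 rose, 4327 to 5244 fell), 568 to 688 and 596 to 742 at 2-fold or more, and 1 to 4 lists (4 without replicate 3). All other settings kept these counts within 1.5 times, and the authors' table called 9317 genes, 8810 of them shared in direction. Of the 1264 genes changed at least 2-fold, at least 1256 were called in the same direction under each other setting that tested 1263 or more of them, apart from 956 unpaired and 1216 against a fold of 1.5. With the unnormalized scanner medians the median of all genes was -0.09 (in place of -0.0065), with 41.6% rises among calls. That setting and the authors' table moved TMSB15A (to 4.77 and 4.62) and CLCA2 (to -3.56 and -3.61) by over 1.5 times. Among the other genes printed, the scanner medians moved MX1 (to -4.20), ITGB2 (-2.39), TAC3 (3.09), MAEL (3.97), SLC46A3 (4.39), ELOVL4 (3.33) and FABP4 (4.49) as much, the authors' table DDX4 (to 2.20), and a normexp offset of 10 MAEL (3.48), SLC46A3 (3.67) and FABP4 (2.62). The variant within a slide was not run, since each array is its own slide. Signal over background limits the dim genes, with 21906 of 26964 kept probes above background in both channels on all arrays.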

Other observations

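The tests of small changes and of the metallothioneins were chosen after the results were seen, and the others were set before their values were known. The test of neighbouring genes was chosen in place of a test of X-linked genes, which was run first and met its prediction of more 2-fold rises, with an interval that included no excess once cancer-testis families were left out. It was dropped after its result had been seen, because the gene table, of a build the files do not name, was used only for names and for which genes are neighbours. Beyond the lists already described, the 2-fold changes fell unevenly over the range of signal. Without a filter, 173 genes rose and 94 fell at least 2-fold in the dimmest of 3 equal parts of the genes, against 283 and 373 in the middle part and 243 and 265 in the brightest.

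Turning the sign of 1 array at a time gave 4 sign patterns in all, of which 1, the real one, called 19532 probes, and the highest of the others called 0 (limma; at most 25 probes at an unadjusted p under 0.05). With 4 patterns no share under 0.05 is possible.

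Most called genes changed by less than 1.5-fold on arrays of 1 dye orientation. If effects of single probes or of their labelling were the cause, different probes of a gene would often disagree. Among 2280 genes called at under 1.5-fold with a further kept probe, the 2 brightest probes shared their sign in 77.0% (exact binomial interval 75.2% to 78.7%), between the bounds set for such effects (under 60%) and against them (over 80%). The share was 91.3% for calls from 1.5-fold to 2-fold, 95.6% at 2-fold or more and 59.7% for genes not past the threshold. Part of the small calls may therefore be probe effects, VPA stays open for the rest, and a dye effect common to the whole transcript cannot be told apart from VPA here.

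Probes above background only with VPA outnumbered those only in control by 265 to 5. A wider background in the Cy3 channel may account for most of this: its median SD was 152, 138 and 186, against 43, 79 and 75 in Cy5, and with 1 threshold for both channels (the 35th percentile of all values) and at least a 2-fold difference the counts were 116 and 85, a ratio of 1.37 (exact interval 1.02 to 1.83, bound set at 2). Of the 265 probes, 41 were brighter in the control channel and 48 had a bound of 2-fold or more. The alternative that VPA raised mostly genes of low signal predicts more rises among dim genes, and the share of rises at 2-fold or more was 17.0 percentage points higher in the dimmest than in the brightest part (SE 3.67). That lies in the predicted direction but exceeds the bound of 10 by less than 2 SE, so the test cannot decide. The dimmest part held fewer decreases (94 against 265) and also fewer rises (173 against 243) than the brightest. The normexp offset shrinks ratios near background and may lower both counts, but the parts were not counted at another offset. The alternative that VPA raised mostly genes of low signal stays open.

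Of the 9 measured MT1 and MT2 genes, 8 rose at least 2-fold, and their sequences are alike. The 12 probes with a mean log2 signal over 11 ran from 0.30 (MT1B) to 3.07, a range of 11.6 median SDs (5.67 without MT1B). The 3 probes of MT2A alone spanned 5.54 median SDs, about as wide as the family without MT1B. The lowest of them varied widely over the arrays (1.74 ± 1.36), while the other 2 gave 2.54 ± 0.35 and 3.07 ± 0.33. With that probe included, the bound of 4 SDs set for separate transcripts was too low, and this comparison rests on it. Whether the 8 genes rose separately or 1 or a few transcripts were read by several probes cannot be told apart here, and VPA stays open as the cause of the rise.

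The hypothesis that neighbouring genes changed together was tested over 12095 neighbouring pairs of measured protein-coding genes. Pairs whose symbols begin with the same letters were left out as 1 family, so related neighbours with unlike symbols stayed in. Pairs that both rose at least 2-fold numbered 34, against a mean of 23.6 in 10000 shuffled gene orders, 1.44 times as many (exact Poisson interval 0.996 to 2.01, permutation p = 0.021, one-sided). For decreases there were 38 pairs against 27.3 (permutation p = 0.025, one-sided). The ratio lay between the bounds set for and against the hypothesis, and genes that share transcripts or probes may add to it. The correlation of neighbouring log2 ratios across genes, which are not independent replicates, was 0.08.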
